A study of Mus musculus with 12 samples.

How the data were processed

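Total RNA of mouse spinal cord was measured on 12 one-colour Affymetrix 3' expression arrays, 1 biotin-labelled sample per array. Groups were taken from the submitters' labels: wild type at day 4, Olig2cre/DA-Cat at day 4, wild type at day 15 and Olig2cre/DA-Cat at day 15, with 3 biological replicates each. Replicates are named by the numbers in the sample titles. The labels call each replicate biological and do not say how many animals a sample holds. Day is tagged as a developmental stage, whereas the treatment protocol in the same labels describes lysolecithin lesions of 8- to 10-week-old adults, collected unlesioned or 14 days after the lesion. Neither 4 nor 15 days occurs in that protocol, so what the days are counted from was left open in all comparisons. Per the labels' protocols, 0.5 μL of 1% lysolecithin was injected, tissue was cut out by hand from about 80 cryosections of 50 μm per cord, and RNA integrity was checked on a Bioanalyzer.

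The deposited values were 1 log2 signal per probe set and array, from the series' value table. How the authors corrected the background, summarised probes and normalized between arrays is not given in the sources used here. That the scale is log2 was judged from the values: array medians lay between 6.14 and 6.19, lower quartiles between 4.48 and 4.57, upper quartiles between 8.14 and 8.23, and maxima between 14.71 and 15.05. The 12 distributions were thus nearly equal, and a shift shared by most genes could not be seen in them. No detection call, scan date or scanner file was used here, and no batch is named in the labels. Array data carry no read depth; the number of arrays limits the precision. The median residual SD over genes was 0.11 log2 and its 95th percentile 0.22.

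Of 45101 probe sets, 34958 had 1 gene symbol in the platform annotation, 932 had several and 9211 were not listed there with a gene and stayed unnamed. Symbols were checked through Entrez identifiers against a RefSeq gene table of assembly GRCm38.p6; 34754 of the 1-symbol probe sets matched and 0 symbols had to be changed. Only names were taken from that table, and no coordinates are given, since the deposited table names no genome build. For each gene the probe set with the highest mean over the 12 arrays was kept, which left 18194 genes; 9012 of them had more than 1 probe set. Genes were not filtered by brightness.

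All 12 arrays were fitted together with 1 mean per group in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit and eBayes without trend and without robust settings). The fit had 8 residual degrees of freedom and 3.96 prior degrees of freedom. Contrasts were Olig2cre/DA-Cat minus wild type at day 4, at day 15 and on average over both days, day 15 minus day 4 in each genotype, and the difference of the 2 genotype effects. P-values were two-sided and Benjamini-Hochberg adjusted over the genes, with a threshold of 0.05. Adjusted p-values of single genes in all parts come from this limma fit.

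Before the data were examined, 30 gene lists were fixed for pathways and cell types: Wnt targets and feedback; Wnt ligands, receptors and transducers; myelin and mature oligodendrocyte; oligodendrocyte precursor; newly formed oligodendrocyte; inhibitors of oligodendrocyte differentiation; cholesterol synthesis; myelin glycolipid synthesis; cell cycle; astrocyte; reactive astrocyte; neuron; motor neuron; immature nervous system; microglia and macrophage; lipid-laden phagocyte; endothelium; pericyte and smooth muscle; meninges and fibroblast; Schwann cell, ependyma, red blood cell, skeletal muscle, cartilage and bone, interferon response, amino acid and endoplasmic reticulum stress response, immediate early genes, brachial and thoracic Hox, lumbosacral Hox, and sex-linked genes. Of 517 list entries, 482 had a named probe set, and the other 35 were not analysed here. Each list was tested with camera at its preset inter-gene correlation of 0.01, adjusted over the lists within a contrast. Camera with an estimated correlation and fry were alternatives. Counts of list members are given over all genes, and where stated also adjusted over the list alone.

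Genes named in the text followed a rule fixed in advance. For both genotype contrasts it took a fixed panel (Ctnnb1, Olig2, Axin2, Lef1, Nkd1, Sp5, Notum, Apcdd1, Tcf7l2, Id2, Mbp, Mag, Mog, Pdgfra and Gfap; a further panel member was not analysed here), and up to 8 genes with the highest and 8 with the lowest log2 difference among genes past the threshold whose 3 values per group did not overlap. The average and day contrasts took 6 and 6, the difference between days the 6 genes with the smallest p, and every list described up to 4 members with the smallest p. Clone names and sex-linked genes were passed over. A gene named outside the rule is said to have been chosen after its values were seen.

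The fit was tested on simulated arrays of 18194 genes, of which 100 were changed by 0.5 log2 and 100 by 1 log2. For the day 4 genotype contrast it recovered 95.0% of genes changed by 1 log2 and 72.0% of those changed by 0.5 log2, and for the day 15 genotype contrast 94.0% and 63.0%. For the difference between days it recovered 86.0% and 40.0%. Between 6 and 11 unchanged genes were called in a contrast, the 11 for day in wild type. The noise was drawn independently for each gene and array. Variation shared by many genes, such as uneven muscle RNA, was thus not simulated, and the shares may be too high for the real arrays.

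Alternatives planned in advance were quantile normalization, centring of each array on its median, leaving out the dimmest 30% or 50% of genes, the most variable probe set of a gene, the mean of its probe sets, every probe set on its own, eBayes with trend and robust settings, a fit on only the 2 groups compared, array weights, the replicate number as a block, leaving out each array in turn, a 2-fold minimum, an adjusted p under 0.01, and the list tests named above. Added after the data were seen were the skeletal muscle level of each array as a covariate, the Eif2s3y level of each array as a covariate, and leaving out 3 arrays with RNA of 1 sex. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.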

Results

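The data were gene expression levels of spinal cord from wild-type mice and Olig2cre/DA-Cat littermates, sampled at day 4 and at day 15. The sample titles name the tissue as spinal cord. They do not say whether it was ventrolateral white matter alone. Neuron genes had a mean level between 11.44 and 11.73 on the 12 arrays, far over the array medians, which argues against white matter alone. Which parts of the cord were taken was left open. Olig2cre brings Cre recombinase to cells that use the Olig2 gene, a transcription factor of the oligodendrocyte lineage, and DA-Cat stands for a dominant-active form of β-catenin, the transducer of canonical Wnt signalling. Each of the 4 groups held 3 arrays, and 18194 genes were tested. Levels are log2 signals, given as mean ± SD with n = 3 arrays per group, and differences are log2. The median level of an array lay between 6.14 and 6.19. Bacterial control probe sets had a median of 3.07. Differences that start or end at a group mean under 5, a level chosen after the values were seen, were read as limited by background, which held for Wif1, Prss56, Rnf43, Sp5, Srpx, Cdh1 and Nipal4 among the genes named below. The mean correlation of an array with the others of its group, across all probe sets, lay between 0.994 and 0.997. The first principal component held 72.5% of the variance and parted the days, and the next held 10.1%. What the days are counted from was left open, since the labels tag them as developmental stages while their protocol describes adult lesions. Microglia and myosin levels given further below argue against days after an adult lesion, without settling it. No group with Cre alone was included, so the genotype contrast holds Cre and DA-Cat together.

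The first comparison asked how constant Wnt signalling in Olig2-expressing cells changed the tissue at day 4. Of 27 myelin genes 23 fell, and of 19 Wnt targets and feedback genes 9 rose and 1 fell. Mog, a protein of the outer myelin surface, was at 8.93 ± 0.14 in wild type and 5.47 ± 0.35 in Olig2cre/DA-Cat, a difference of -3.46 ± 0.16 (SE, adjusted p = 9.6e-08). Mobp, a myelin structural protein, differed by -3.02 ± 0.08 (SE, adjusted p = 2.53e-09), from 12.38 ± 0.08 to 9.36 ± 0.12. Wif1, a secreted inhibitor of Wnt ligands, went from 4.13 ± 0.31 to 6.96 ± 0.35 and was higher by 2.83 ± 0.18 (SE, adjusted p = 1.73e-06).

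Of 27 measured members of the myelin and mature oligodendrocyte list, 23 fell at day 4 and 0 rose (25 and 0 adjusted over the list alone), with a median of -1.74 and a list adjusted p = 2.84e-63. Mbp, which compacts myelin, was at -1.70 on a probe set near the array maximum, and between -2.58 and -0.024 over its 8 probe sets. Mag was at -2.48, Tmem88b at -2.80 and Fa2h, which makes the hydroxylated fatty acids of myelin lipids, at -2.27. Among genes with the lowest differences were also Ermn at -3.33, the tight junction protein Cldn11 at -2.64, the protease Adamts4 at -2.61, Nipal4 at -2.56 and Ugt8a, the galactocerebroside synthase, at -2.53. The myelin glycolipid synthesis list had 9 of 16 members lower and 0 higher (10 and 0 adjusted over the list alone), with a median of -0.33 and adjusted p = 1.79e-17. Its other members with the smallest p were the fatty acid elongases Elovl7 at -1.95 and Elovl1 at -1.06. Of 18 members of the newly formed oligodendrocyte list 12 fell and 0 rose (14 and 0 adjusted over the list alone; median -0.71, adjusted p = 1.03e-22), among them Enpp6 at -2.18, Bcas1 at -1.58, Sirt2 at -1.50 and Nfasc at -1.46. These 3 lists and the Wnt target list were called with an estimated correlation as well.

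Smaller differences were found in other lists of the lineage at day 4. Of 18 precursor genes 6 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.27, adjusted p = 5.37e-07 and adjusted p = 0.337 with an estimated correlation. Those that fell included the transcription factors Sox10 at -1.06 and Olig2 at -0.90 ± 0.10 (SE, adjusted p = 0.000171), the matrix protein Tnr at -0.92, and C1ql1 at -0.42. Without a group with Cre alone, a part of Olig2cre in the lower Olig2 level cannot be told apart from that of DA-Cat. Pdgfra, the growth factor receptor of precursors, differed by -0.24 and did not pass (adjusted p = 0.138). Of 19 cholesterol synthesis genes 6 fell and 0 rose (10 and 0 adjusted over the list alone; median -0.27, adjusted p = 1.49e-09, adjusted p = 0.482 with an estimated correlation), with Lss at -0.67, Idi1 at -0.60, Sc5d at -0.53 and Hmgcs1 at -0.39. The list of inhibitors of oligodendrocyte differentiation was not called (adjusted p = 0.972); 2 of its 17 members fell and 0 rose (2 and 0 adjusted over the list alone), Gpr17 at -1.41 and Bmp4 at -0.73, and Id2 differed by 0.01 (adjusted p = 0.975).

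Of 19 measured Wnt targets and feedback genes 9 rose and 1, Ccnd1, fell by 0.54 at day 4 (10 and 1 adjusted over the list alone), with a median of 0.33, adjusted p = 1.65e-07 and adjusted p = 0.0091 with an estimated correlation. Nkd1, which acts on Dishevelled, rose by 2.15, Notum, which inactivates Wnt ligands, by 2.09, the transcription factor Sp5 by 1.35, the ubiquitin ligase Rnf43 by 1.28, Axin2, a scaffold of the β-catenin destruction complex, by 1.05, the transcription factor Lef1 by 0.70 and Apcdd1 by 0.63. Outside this list, the serine protease Prss56 rose by 3.54, from 4.45 ± 0.09, near background, to 7.99 ± 0.19, the muscle myosin-binding protein gene Mybpc1 by 2.97 and Esyt3 by 1.68. The skeletal muscle list had a median of 0.89 at day 4 with 11 of 12 genes of positive sign and was not called (adjusted p = 0.531). Ctnnb1, the gene of β-catenin, differed by -0.05 (adjusted p = 0.696). Tcf7l2, a transcriptional partner of β-catenin, fell by 0.75 (adjusted p = 0.0124). In the list of 48 Wnt ligands, receptors and transducers Fzd1 rose by 0.39 and Fzd2 by 0.32, and the list was not called (adjusted p = 0.373; 4 higher and 1 lower adjusted over the list alone). Gfap, the astrocyte filament, fell by 0.41 (adjusted p = 0.0418), whereas the astrocyte list was not called (adjusted p = 0.125).

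In all, 567 genes differed between the genotypes at day 4, 237 higher and 330 lower in Olig2cre/DA-Cat, and 82 of them by at least 2-fold (10 higher, 72 lower). Which direction held more genes depended on the setting: 125 higher and 382 lower with quantile normalization, but 464 and 389 without the dimmest 30% of genes, 618 and 391 without the dimmest 50%, 437 and 407 with trend and robust settings, 1327 and 837 with array weights, and 349 and 322 without wild type replicate 3. The count was 260 without wild type replicate 1 (54 higher, 206 lower), 306 without wild type replicate 2 (59 and 247), 260 without Olig2cre/DA-Cat replicate 2 (57 and 203) and 261 without Olig2cre/DA-Cat replicate 3 (52 and 209).

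**Figure D1:**
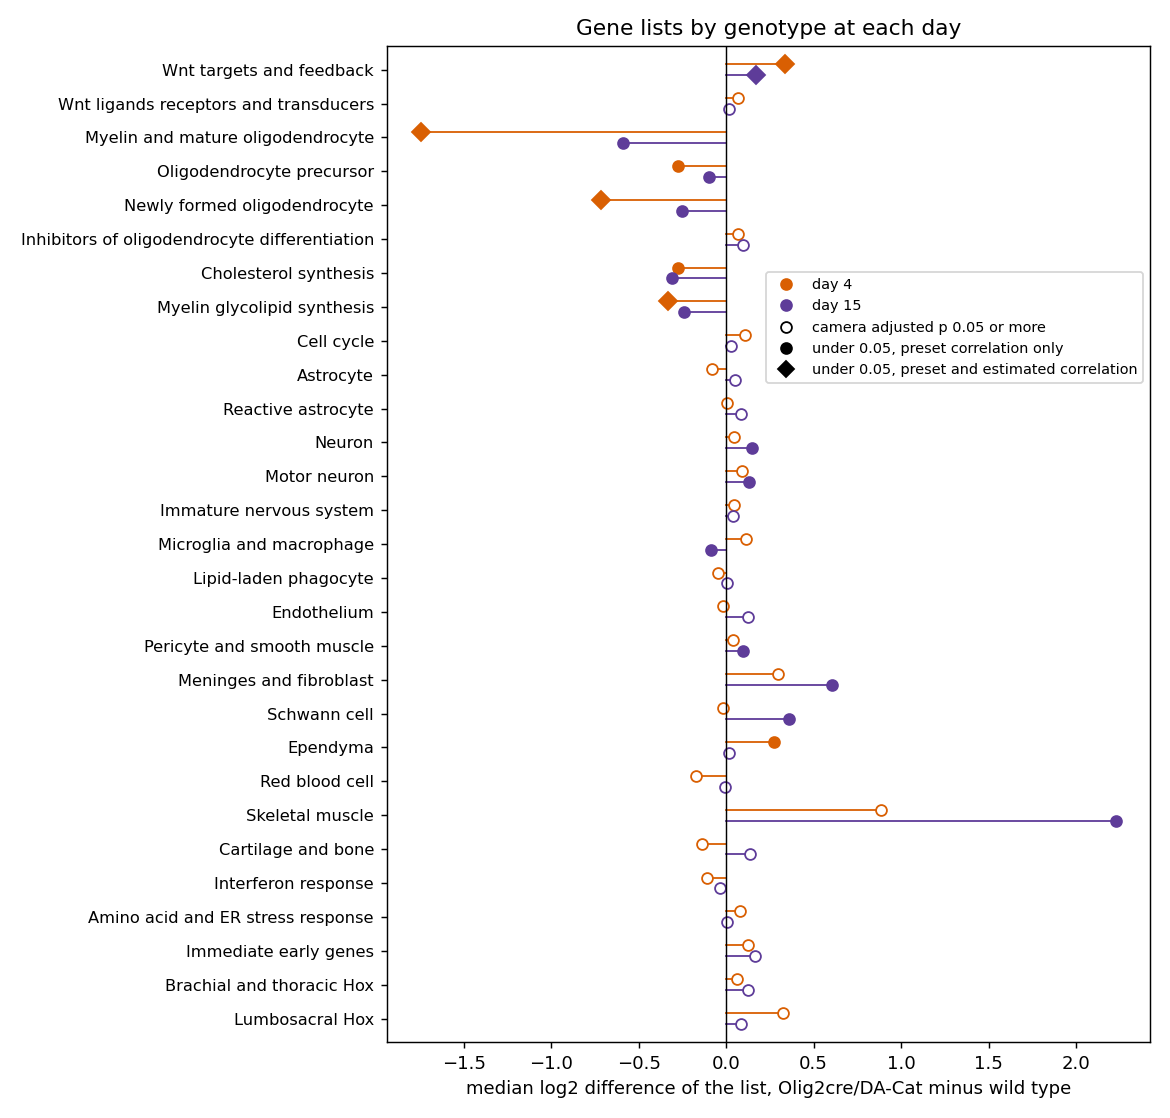
Median log2 difference between Olig2cre/DA-Cat and wild type (x axis) for 29 gene lists (y axis) at day 4 and at day 15. Filled points passed an adjusted p of 0.05 with the preset correlation and diamonds also with an estimated correlation; the myelin list lay at -1.74 at day 4 and -0.59 at day 15.

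In the same comparison at day 15, 19 of 27 myelin genes fell and 5 of 19 Wnt targets and feedback genes rose. The myelin list had adjusted p = 1.32e-31, and adjusted p = 0.0744 with an estimated correlation. Wif1 rose by 2.85 ± 0.18 (SE, adjusted p = 2.99e-05), from 3.80 ± 0.15 to 6.65 ± 0.14. Aspa, the enzyme that breaks down N-acetylaspartate in oligodendrocytes, went from 11.37 ± 0.12 to 10.24 ± 0.22 and fell by 1.12 (adjusted p = 0.000729). Mbp was at 14.66 ± 0.02 in wild type and 14.62 ± 0.03 in Olig2cre/DA-Cat (adjusted p = 0.779), close to the lowest array maximum of 14.71, so a difference could not be read from this probe set. Over its 8 probe sets the difference lay between -0.29 and 0.073. The chemokine receptor Cxcr4 rose by 1.58 ± 0.11 (SE, adjusted p = 6.37e-05).

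Of the 27 myelin genes 19 fell and 0 rose at day 15 (26 and 0 adjusted over the list alone), with a median of -0.59, adjusted p = 1.32e-31 and adjusted p = 0.0744 with an estimated correlation. Those with the smallest p were Hapln2, a protein of the node of Ranvier, at -1.07, Aspa, Evi2a at -0.83 and Fa2h at -0.72. Mog differed by -0.85 (adjusted p = 0.013) and Mag by -0.53 (adjusted p = 0.024). Other low genes were Anln at -1.22, Klhl4 at -1.18, Nmral1 at -1.09, the carboxypeptidase Cpm at -1.05, Pdlim2 at -1.04 and the tetraspanin Cd82 at -1.02. Of the glycolipid list 5 of 16 fell and 0 rose (13 and 0 adjusted over the list alone; median -0.24, adjusted p = 3.87e-12, adjusted p = 0.0817 with an estimated correlation), among them the ceramide synthase Cers2 at -0.63. The cholesterol list also had 6 of 19 lower and 0 higher (12 and 0 adjusted over the list alone; median -0.31, adjusted p = 3.87e-12, adjusted p = 0.383 with an estimated correlation), with Lss at -0.57, Msmo1 at -0.52, Cyp51 at -0.46 and Sc5d at -0.43.

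Of 18 newly formed oligodendrocyte genes 3 fell and 0 rose at day 15 (5 and 0 adjusted over the list alone), with a median of -0.25, adjusted p = 4.97e-06 and adjusted p = 0.489 with an estimated correlation. They were the transcription factors Nkx6-2 at -0.91 and Myrf, which switches on myelin genes, at -0.77, and Enpp6 at -0.65. Of 18 precursor genes Sox10 at -0.61 and Olig2 at -0.44 (adjusted p = 0.0278) fell and 0 rose (5 lower and 1 higher adjusted over the list alone); the list adjusted p was 0.0485, and adjusted p = 0.665 with an estimated correlation. Pdgfra differed by -0.09 (adjusted p = 0.654) and Gfap by -0.06 (adjusted p = 0.818).

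Of the 19 Wnt targets and feedback genes 5 rose and 0 fell at day 15 (8 and 0 adjusted over the list alone), with a median of 0.17, adjusted p = 1.22e-06 and adjusted p = 0.0216 with an estimated correlation. Besides Wif1 these were Notum at 1.14, Tnfrsf19 at 0.62, Axin2 at 0.51 and the R-spondin receptor Lgr5 at 0.51. Lef1 at 0.23, Nkd1 at 0.30, Sp5 at 0.17, Apcdd1 at 0.40, Tcf7l2 at -0.34, Id2 at 0.10 and Ctnnb1 at -0.07 did not pass. The genes with the highest differences further included Mybpc1 at 2.52, Prss56 at 1.86, Srpx at 1.71, the peripheral myelin gene Ncmap at 1.25, Esyt3 at 1.20 and the cell adhesion protein Cdh1 at 1.20.

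Lists of other tissues were also called at day 15, and none of these calls held with an estimated correlation. The skeletal muscle list had a median of 2.23 with 0 of 12 genes called (adjusted p = 0.0123, adjusted p = 0.665 with an estimated correlation; 0 adjusted over the list alone). Its mean level was 10.65, 5.26 and 8.48 on the Olig2cre/DA-Cat arrays and 6.35, 5.11 and 7.24 on those of wild type. The meninges and fibroblast list had a median of 0.60 with 0 of 14 genes called (adjusted p = 0.00012, adjusted p = 0.604 with an estimated correlation). The Schwann cell list had a median of 0.36, and Ncmap alone of its 9 genes passed (5 higher and 1 lower adjusted over the list alone; adjusted p = 0.0123, adjusted p = 0.383 with an estimated correlation). Medians were 0.15 for the neuron list (0 of 19 genes called, 2 higher and 0 lower adjusted over the list alone; adjusted p = 0.000514, adjusted p = 0.604 with an estimated correlation), 0.13 for motor neuron genes (0 of 14 called; adjusted p = 0.00665, adjusted p = 0.588 with an estimated correlation), 0.10 for pericyte and smooth muscle genes (0 of 11 called; adjusted p = 0.0123, adjusted p = 0.604 with an estimated correlation) and -0.09 for microglia and macrophage genes (0 of 18 called; adjusted p = 0.0152, adjusted p = 0.649 with an estimated correlation).

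In all, 533 genes differed between the genotypes at day 15, 112 higher and 421 lower, and 20 by at least 2-fold (10 higher, 10 lower). The count was 292 without wild type replicate 1 (36 higher, 256 lower), 935 without Olig2cre/DA-Cat replicate 2 (328 and 607) and 299 without Olig2cre/DA-Cat replicate 3 (46 and 253). With the muscle level of each array as a covariate it was 301 (44 and 257), with the level of Eif2s3y 930 (312 and 618), and from the day 15 arrays alone 136 (18 and 118).

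**Figure D2:**
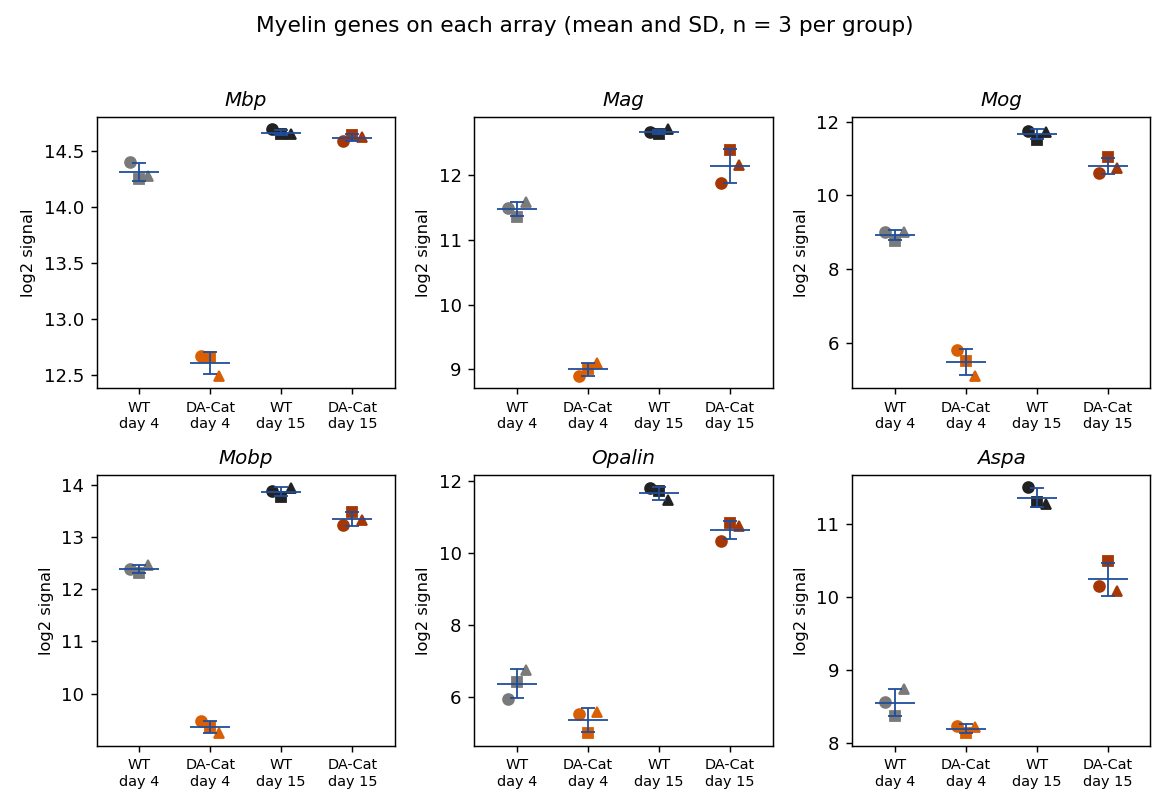
Log2 signal (y axis) of myelin genes in the 4 groups, with 1 point per array, point shapes for replicates 1 to 3 and bars for mean ± SD (n = 3). Mog lay at 8.93 in wild type and 5.47 in Olig2cre/DA-Cat at day 4, and at 11.65 and 10.80 at day 15.

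The difference between the days was tested directly. Of the 27 myelin genes 16 had a positive difference past the threshold, towards wild type, and 0 a negative one (22 and 3 adjusted over the list alone), with a median of 1.22, adjusted p = 8.47e-39 and adjusted p = 0.0832 with an estimated correlation. The sign was negative for 5 of them, among which Aspa was at -0.36 at day 4 and -1.12 at day 15, a difference of -0.76 (adjusted p = 0.0906). Mobp changed by 2.50 ± 0.12 (SE, adjusted p = 1.41e-06), Ermn by 2.45, Tmem88b by 2.01, Mag by 1.95 and Fa2h by 1.55. Mbp differed by 1.65 (adjusted p = 4.15e-06) on a probe set near the array maximum, and by 0.097 to 2.29 over its 8 probe sets. For all 27 the day 15 mean of Olig2cre/DA-Cat lay between the wild-type means of day 4 and day 15. The newly formed oligodendrocyte list had a median of 0.52 with 4 of 18 higher and 0 lower (9 and 0 adjusted over the list alone; adjusted p = 2.28e-12, adjusted p = 0.241 with an estimated correlation), namely Enpp6 at 1.54, Bcas1 at 1.35, Sirt2 at 1.17 and Nfasc at 1.17. In the precursor list Tnr changed by 0.76 (3 higher and 0 lower adjusted over the list alone; list median 0.19, adjusted p = 0.000144, adjusted p = 0.453 with an estimated correlation).

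The effect on some Wnt feedback genes shrank. Nkd1 changed by -1.85 ± 0.20 (SE, adjusted p = 0.000935) and Sp5 by -1.18 ± 0.19 (SE, adjusted p = 0.0186), and these 2 were the only called genes of the Wnt list (2 higher and 5 lower adjusted over the list alone; median -0.19, adjusted p = 0.0255, adjusted p = 0.241 with an estimated correlation). The difference for Wif1 was 0.02 (adjusted p = 0.987), but its wild-type levels of 4.13 and 3.80 lay near background, which limits both of its genotype differences; those of Sp5 (4.83 and 4.54) did too. Over all genes 64 had an effect that differed, 35 with a positive and 29 with a negative difference, and 48 and 25 with quantile normalization. Negative differences were more frequent with trend and robust settings (47 positive, 61 negative), without the dimmest 50% (55 and 62), with array weights (56 and 62), with the Eif2s3y covariate (28 and 30) and without Olig2cre/DA-Cat day 15 replicate 2 (39 and 40), and with centred arrays both were 32.

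**Figure D3:**
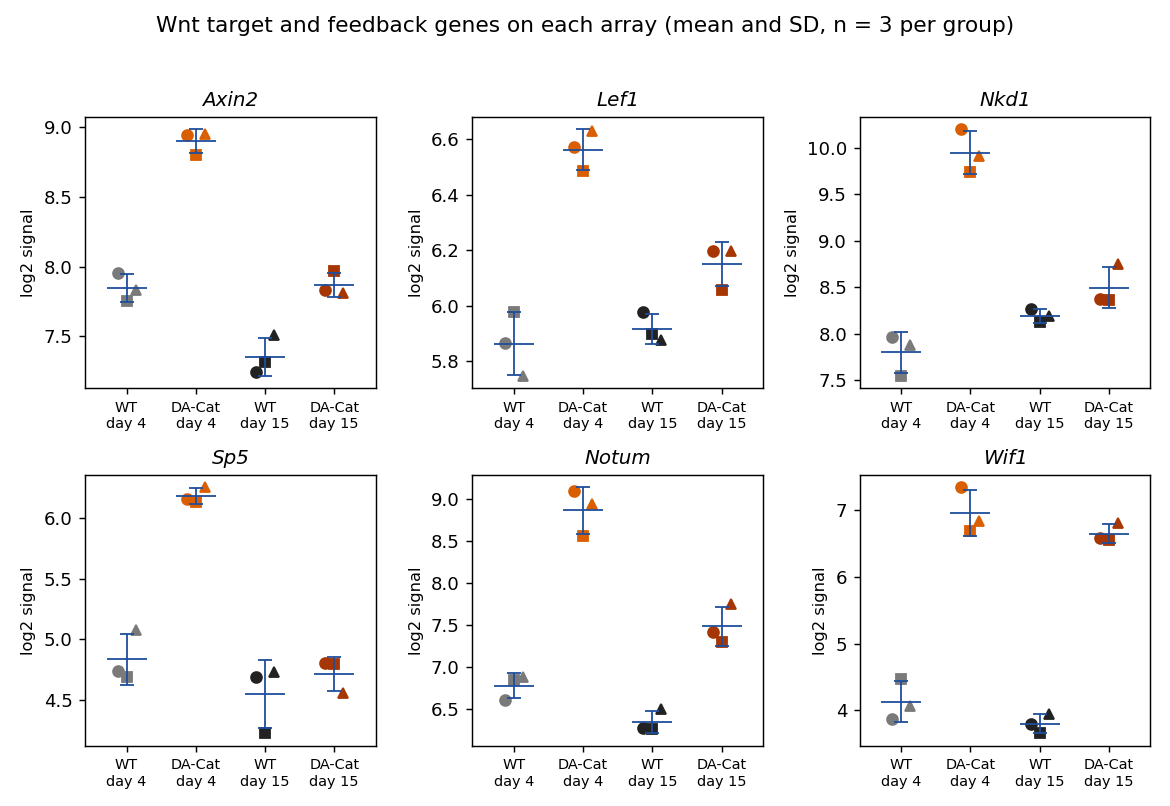
Log2 signal (y axis) of Wnt pathway genes in the 4 groups, with 1 point per array, point shapes for replicates 1 to 3 and bars for mean ± SD (n = 3). Wif1 was higher in Olig2cre/DA-Cat by 2.83 at day 4 and 2.85 at day 15, and Nkd1 by 2.15 and 0.30; wild-type Wif1 lay near background.

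The genes changed at both days overlapped. Of those higher in Olig2cre/DA-Cat 27 were shared where 1.46 would be by independence (Fisher's exact p = 6.83e-27), and of those lower 153 where 7.64 would be (Fisher's exact p = 4.99e-168). These p-values treat genes as independent units, which they are not. Both contrasts also use the same estimate of spread per gene, which by itself raises the overlap, so the p-values are too small. Chosen after their values were seen, Gli1, a transcription factor of Hedgehog signalling, and Rspo3, a secreted enhancer of Wnt signalling, were among the shared higher genes. Opposite changes were found for 3 genes, named after their values were seen: Pld6 (0.63 at day 4, -0.35 at day 15), Sh3bp2 (0.59, -0.79) and Tbc1d16 (0.33, -0.33). Across genes, which are not independent replicates, the differences of both days correlated with r = 0.45 and rho = 0.36.

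**Figure D4:**
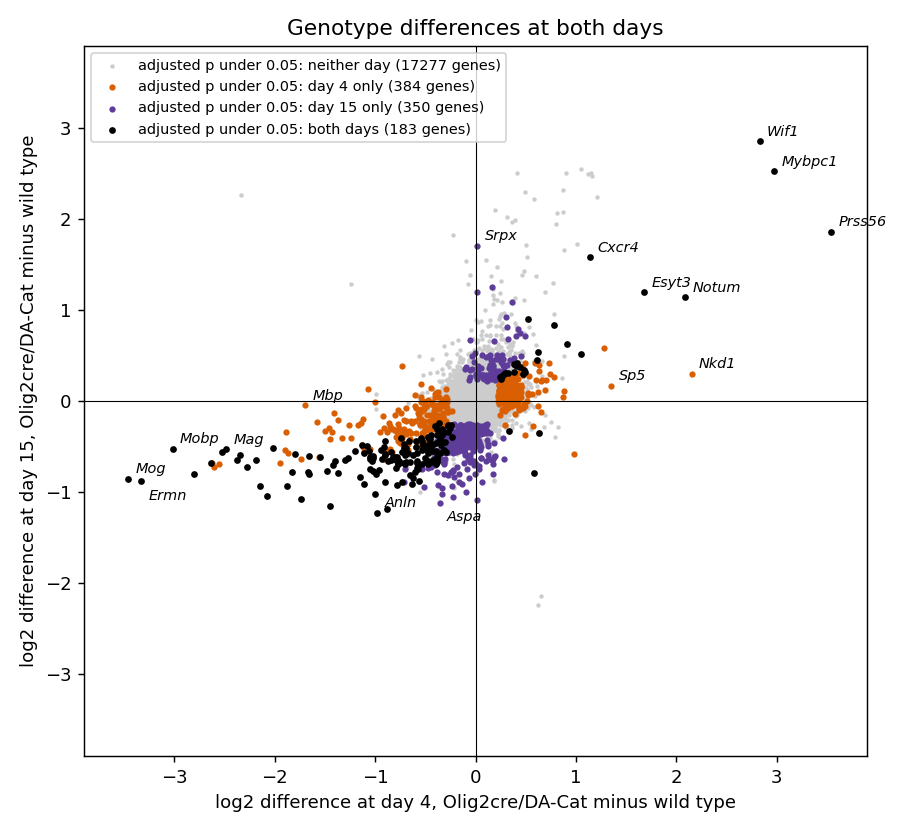
Log2 genotype difference of 18194 genes at day 4 (x axis) against that at day 15 (y axis), with 1 point per gene coloured by the days at which it passed. Of these genes 183 passed at both days, 384 at day 4 alone and 350 at day 15 alone.

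On average over both days the genotype contrast was led by the same kinds of genes. Among the highest were Wif1 at 2.84, Mybpc1 at 2.75, Prss56 at 2.70, Notum at 1.62, Esyt3 at 1.44 and Cxcr4 at 1.36; their order was not read, since background limits Wif1 and Prss56. Among the lowest were Mog at -2.16, Ermn at -2.11, Tmem88b at -1.80, Mobp at -1.77, Cldn11 at -1.66 and Nipal4 at -1.63. All 27 myelin genes were lower (median -1.19, adjusted p = 0.0138 with an estimated correlation), 10 of 19 Wnt genes were higher and 0 lower (median 0.29, adjusted p = 0.0103 with an estimated correlation). In all 1512 genes differed, 763 higher and 749 lower, and which direction held more depended on the setting. More were higher than lower without the dimmest 30% (1167 and 850) or 50% (1328 and 819), with trend and robust settings (1095 and 874), with array weights (1851 and 1155), with the replicate block (828 and 762) and with the Eif2s3y covariate (1248 and 1028, in all 2276). More were lower with quantile normalization (504 higher and 817 lower), centred arrays (509 and 758), the most variable probe set (597 and 696), the mean of probe sets (651 and 682), every probe set on its own (754 and 1175), a 2-fold minimum (7 and 40), an adjusted p under 0.01 (154 and 409), the muscle covariate (255 and 486, in all 741) and without the 3 arrays with RNA of 1 sex (370 and 574, in all 944). Without 1 array, more were lower without wild type day 4 replicate 1 (347 and 561, in all 908) or 2 (373 and 605, in all 978), wild type day 15 replicate 1 (405 and 614) or 2 (436 and 623), Olig2cre/DA-Cat day 4 replicate 1 (545 and 651), 2 (359 and 547, in all 906) or 3 (310 and 558, in all 868), and Olig2cre/DA-Cat day 15 replicate 1 (595 and 650) or 3 (347 and 559, in all 906). More were higher without wild type day 4 replicate 3 (949 and 725), wild type day 15 replicate 3 (767 and 651) or Olig2cre/DA-Cat day 15 replicate 2 (1268 and 988).

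From day 4 to day 15 in wild type, myelin genes rose, and genes of cell division and of immature neurons fell. Opalin, a membrane protein of oligodendrocytes, rose by 5.30 ± 0.21 (SE, adjusted p = 7e-09), Fam107a by 4.80, the protease Klk6 by 4.66, Kcng4 by 3.62, the calcium buffer Pvalb by 3.57 and the immunoglobulin heavy chain Ighm by 3.12. The virus and adhesion receptor Cxadr fell by 3.38, Ablim3 by 2.77, Col14a1 by 2.73, the meiotic gene Syce2 by 2.72, the GTPase Rac3 by 2.59 and Syt17 by 2.58. All 27 myelin genes rose (27 and 0 adjusted over the list alone; median 1.80, adjusted p = 1.17e-21, adjusted p = 0.198 with an estimated correlation). Of 25 cell cycle genes 23 fell and 0 rose (23 and 0 adjusted over the list alone; median -1.26, adjusted p = 1.76e-10, adjusted p = 0.407 with an estimated correlation), with the ribonucleotide reductase Rrm2 at -2.18. Of 19 immature nervous system genes 16 fell and 0 rose (18 and 0 adjusted over the list alone; median -0.99, adjusted p = 2.72e-08, adjusted p = 0.137 with an estimated correlation), with Crmp1 at -2.49 and Gap43 at -1.97. Of 18 microglia and macrophage genes 16 rose and 0 fell (16 and 0 adjusted over the list alone; median 0.66, adjusted p = 4.83e-07, adjusted p = 0.379 with an estimated correlation), with Tmem119 at 0.78.

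From day 4 to day 15 in Olig2cre/DA-Cat, Klk6 rose by 5.55 ± 0.18 (SE, adjusted p = 9.71e-10), Mog by 5.33, Opalin by 5.28, Ermn by 5.12, Pvalb by 4.48 and Fam107a by 4.41. Of these 6, the rise differed from that in wild type for Mog (2.61, adjusted p = 0.000144) and Ermn (2.45, adjusted p = 9.63e-05), and the difference did not pass for Klk6 (0.89, adjusted p = 0.263), Pvalb (0.91, adjusted p = 0.495), Fam107a (-0.39, adjusted p = 0.758) and Opalin (-0.02, adjusted p = 0.989). Cxadr fell by 3.76, Ablim3 by 2.99, the microtubule protein Dcx by 2.97, Syce2 by 2.96, the polysialyltransferase St8sia2 by 2.95 and Rac3 by 2.94. All 27 myelin genes rose (27 and 0 adjusted over the list alone; median 3.00, adjusted p = 3.56e-26, adjusted p = 0.123 with an estimated correlation), and 24 of 25 cell cycle genes fell and 0 rose (24 and 1 adjusted over the list alone). Of 19 Wnt genes 10 fell and 1, Lgr5, rose (11 and 1 adjusted over the list alone; median -0.31, adjusted p = 0.0298, adjusted p = 0.245 with an estimated correlation). No list called between the days was called with an estimated correlation.

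By count, 8161 genes changed with day in wild type, 3869 higher and 4292 lower (but 4023 and 3999 with centred arrays, and 3151 and 3027 without the dimmest 50%), and 8744 in Olig2cre/DA-Cat, 3965 higher and 4779 lower. Of these, 3177 were higher in both genotypes, 3746 lower in both, and 17 changed in opposite directions. Across genes the day differences of both genotypes correlated with r = 0.92 and rho = 0.86. At least 2-fold changes were found for 1032 and 1267 genes.

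Probe sets of some named genes differed in sign from the probe set used. At the day 4 genotype contrast this held for 1 of 3 probe sets of Ctnnb1, Col14a1 and Fam107a, 1 of 2 of Klhl4, 1 of 5 of Cxadr and 1 of 4 of Dcx. At day 15 it held for 1 of 8 probe sets of Mbp, 1 of 3 of Pdgfra, 4 of 5 of Cxadr and 3 of 4 of Dcx. For Id2 only 1 of 3 probe sets, the one used, had its sign at day 4, and the same held at day 15. For Ighm 4 of 11 had the sign of the one used at day 4 and 5 of 11 at day 15. Probe sets of Cd82, Cxadr, Id2, Ighm, Mbp, Nkd1, Nmral1 and Tcf7l2 differed in sign in at least 1 contrast between days. In these contrasts 8 of 11 probe sets of Ighm had the sign of the one used in wild type, and 7 of 11 in Olig2cre/DA-Cat. For Cxadr 4 of 5 had it in Olig2cre/DA-Cat.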

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

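The tests of a signal ceiling, of cell numbers, of a later course, of Xist and Y-linked signals and of the meaning of day were chosen after the results were seen; the relabelling of arrays was planned.

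A test of the difference between the days singled out 64 genes whose genotype effect differed. Those with the smallest p were Mobp (2.50), Mbp (1.65), Fa2h (1.55), Ermn (2.45), Tmem88b (2.01) and Mag (1.95). Among the lists of the lineage and of Wnt targets, medians were -0.19 for Wnt targets and feedback, 1.22 for myelin, 0.19 for precursors and 0.52 for newly formed oligodendrocytes; with an estimated correlation none of the 4 was called (adjusted p = 0.241, 0.0832, 0.453 and 0.241). After the mean genotype difference of each gene, taken with the real labels, was removed, genotype was relabelled within each day. Among 100 of 200 possible relabellings, 1 gave as many genes, the real one, and the highest other gave 16. For the average over both days the real count of 1512 was also reached by 1 of 100, with 284 as the highest other. A share of 1 in 100 is the smallest these draws can give, so chance is made unlikely but not excluded. Relabelling does not address uneven muscle RNA or sex between the groups. The average count was 741 with the muscle covariate and 2276 with the Eif2s3y covariate. The 10 splits of 6 arrays are too few for a share under 0.05; the real and highest other counts were 567 and 3 for genotype at day 4, 533 and 2 at day 15, 8161 and 0 for day in wild type and 8744 and 0 for day in Olig2cre/DA-Cat, each reached by 1 split.

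Of 27 myelin genes 23 were lower in Olig2cre/DA-Cat at day 4 and 19 at day 15, and 16 had a smaller deficit at day 15 by a test of the difference (22 smaller and 3 larger adjusted over the list alone; adjusted p = 0.0832 for the list with an estimated correlation), while 5 had the opposite sign, among them Aspa with -0.36 at day 4 and -1.12 at day 15. A signal ceiling at day 15 could hide a deficit, yet the 7 myelin genes with a wild-type day 15 mean under 11 had a median difference between the days of 0.67, with 4 called higher and 0 lower (camera p = 9.91e-12, p = 0.00307 with an estimated correlation), which argues against a ceiling as the whole cause; for Mbp, whose wild-type day 15 mean lay 0.0445 under the lowest array maximum, a ceiling stays open, and its 2 dimmer probe sets (wild-type day 15 means 7.40 and 8.41) had differences between the days of 0.33 and 0.097. An equal loss of all stages of the lineage would lower precursor and myelin genes alike. The precursor median at day 4 lay 1.47 above that of the myelin list, which argues against such a loss as the whole cause. Fewer mature oligodendrocytes with precursors kept would give the same gap, so that explanation stays open. A later course of myelin gene expression stays open: 27 of 27 myelin genes had a day 15 mean between the wild-type means, and a lasting smaller deficit would give the same, so they cannot be told apart with 2 days. The genotype itself, which the design names, stays open as well.

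Xist, made from the inactive X chromosome of females, and Y-linked genes were both high on 9 of 12 arrays. Cross-hybridisation of Y-linked probe sets would give a steady signal, whereas Eif2s3y ranged over 5.53, Kdm5d over 4.80 and Uty over 1.80 log2 units. Carry-over of a little RNA would leave a small share of 1 sex, and on 9 of 9 arrays the smaller share was over 10%, from 18.7% to 49.7%. RNA of animals of both sexes in 1 sample may account for it: over these 9 arrays Xist fell as Eif2s3y rose (Spearman rho = -0.97, exact permutation p = 0.000165, adjusted p = 0.000825; Pearson r = -0.82, exact permutation p = 0.00909, adjusted p = 0.0152, and -0.83 without the 2 farthest arrays; 5 relations tested). Whether animals were pooled is not given in the sources used here.

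Day 4 and day 15 could be days after a lesion or postnatal ages. After an adult lesion the microglia and macrophage list and the lipid-laden phagocyte list would be higher at day 4; in wild type the first instead had 18 of 18 genes of positive sign from day 4 to day 15 (median 0.66, SD 0.27 over its genes, 16 called higher and 0 lower; adjusted p = 4.83e-07, adjusted p = 0.379 with an estimated correlation), which argues against a lesion, while the other went both ways (median -0.0005, 3 of 14 higher and 2 lower, adjusted p = 0.943), with Gpnmb and Mmp12 at 5.01 and 3.13 at most. Postnatal age may account for the muscle genes: on the 6 day 4 arrays neonatal myosin Myh8 followed Acta1 (r = 0.97, exact permutation p = 0.00694, adjusted p = 0.0152, and 0.99 without the 2 farthest; rho = 1.00, p = 0.00278, adjusted p = 0.00695). On the 6 day 15 arrays adult myosin Myh4 did (r = 0.99, exact permutation p = 0.00278, adjusted p = 0.0139, and 0.98 without the 2 farthest; rho = 0.94, p = 0.0167, adjusted p = 0.0278). Myh8 reached 7.81 on a day 4 array and 4.60 at most at day 15, whereas Myh4 reached 9.92 at day 15. On the 6 day 4 arrays Myh4 was at 4.05 at most, although 3 of them had Acta1 over 10, which argues against adult muscle. Myh4 at day 4 (r = 0.63, exact permutation p = 0.181) and Myh8 at day 15 (r = 0.80, exact permutation p = 0.0514) did not pass. Both lay near background there, so these 2 tests say little. Since regenerating muscle also makes Myh8, the muscle genes alone do not settle the age.

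Probe sets without a gene name here also held a genotype signal, in values outside the comparisons above. Of 9160 such probe sets 20 differed at day 4, 2 higher and 18 lower, between -2.83 and 0.87, and 15 at day 15, 0 higher and 15 lower, between -1.12 and -0.49.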

How the results depend on the processing

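The skeletal muscle covariate, the Eif2s3y covariate and the fit without 3 arrays of 1 sex were tests chosen after the data were seen; the others were planned. Over 784 results for named genes, 392 of them called in the main fit, 18193 of 19002 alternative values (95.7%) kept their side of the threshold. Direction was compared only where the main fit or the alternative called the result. Values called in neither thus count as kept whatever their sign. Of the other values, 451 lost the call, 358 gained it and 0 reversed. Over 180 list results, 67 of them called in the main fit, 4465 of 4794 values (93.1%) were kept by the same rule. Among the rest, 206 lost the call, 117 gained it and 6 reversed. The cause was not tested except where given.

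Counts are in the order genotype at day 4, at day 15, average, day in wild type, day in Olig2cre/DA-Cat and difference between days. A 2-fold minimum, which removes genes, gave 82, 20, 47, 1032, 1267 and 32. An adjusted p under 0.01, likewise stricter, gave 226, 239, 563 and 37 for the 3 genotype counts and the difference. Leaving out 1 array gave ranges of 260 to 752, 292 to 935, 868 to 2256, 7156 to 8304, 7760 to 8819 and 45 to 87. The lowest and highest of the day 4 count came without wild type day 4 replicate 1 (also 260 without Olig2cre/DA-Cat day 4 replicate 2, 261 without its replicate 3 and 306 without wild type day 4 replicate 2) and Olig2cre/DA-Cat day 15 replicate 2. Genotype at day 4 gave 853 and 1009 without the dimmest 30% and 50%, 2164 with array weights and 258 without the arrays of 1 sex. Genotype at day 15 gave 828 without the dimmest 50%, 136 from only 2 groups (fewer samples), 301 with the muscle and 930 with the Eif2s3y covariate. It gave 299 without Olig2cre/DA-Cat day 15 replicate 3. The average gave 3006 with weights, 741 with muscle, 2276 with Eif2s3y and 944 without the arrays of 1 sex; 908, 978, 906 and 906 came without wild type day 4 replicate 1, its replicate 2, Olig2cre/DA-Cat day 4 replicate 2 and day 15 replicate 3. Every probe set on its own gave 14907 and 16100 for day, where more features are tested, and 99 for the difference. The difference gave 117 without the dimmest 50%, 108 with trend and robust settings, 118 with weights and 39 without the arrays of 1 sex. The replicate number as a block gave 604, 501, 1590, 8195, 8809 and 65. In 7 of 18 cases, within and between days, an array matched best with its own number by its deviations from the group mean. Between the genotypes of 1 day, same-number correlations were 0.26, 0.30 and 0.031 at day 4 and 0.17, 0.18 and 0.015 at day 15. Those of unlike numbers lay between -0.31 and 0.079. A pairing within a day thus stays open, and the numbers were not read as pairs in the main fit.

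The precursor list at day 15 was no longer called with quantile normalization (-0.11), centring (-0.12), without the dimmest 30% (-0.10) or 50% (-0.069), with the mean of probe sets (-0.058), 2 groups (-0.10), weights (-0.069), an estimated correlation (-0.10), fry (-0.10), muscle (-0.025) or without the arrays of 1 sex (-0.14). Without 1 array it ranged from -0.17 to -0.024, and the call ended without any 1 of the 6 day 4 arrays (-0.10 each), wild type day 15 replicate 2 (-0.089) or 3 (-0.036), or Olig2cre/DA-Cat day 15 replicate 1 (-0.024). The Wnt list's difference between days lost its call without the dimmest 30% or 50% (-0.23 each), with weights (-0.078), with an estimated correlation (-0.19), and without wild type day 4 replicate 3 (-0.21) or Olig2cre/DA-Cat day 4 replicate 1 (-0.18); without 1 array it ranged from -0.28 to -0.032. An estimated correlation also ended the calls of precursors at day 4 (-0.27), of myelin (-0.59) and newly formed oligodendrocytes (-0.25, also fry) at day 15, and of myelin (1.22), precursors (0.19, also fry; 0.10 with Eif2s3y) and newly formed oligodendrocytes (0.52) between days; it widens the variance of the test and leaves medians as they were. Reversed were skeletal muscle at day 15 with muscle as a covariate (-0.022, by construction), cell cycle at day 15 with Eif2s3y (-0.10) and without the arrays of 1 sex (-0.12), glycolipid synthesis between days with Eif2s3y (-0.042), and pericytes between days with Eif2s3y (-0.053) and without the arrays of 1 sex (-0.020). Pseudocounts and quantile normalization after a transform were not run, since the values are log2, and a fit of 2 groups gives no value for the average or the difference. Signal over background limits dim genes: 15 bacterial control probe sets had a median of 3.07, and 21.2% of genes a mean under 5.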

Other observations

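The tests of unplanned genes here were chosen after the values were seen; the gene lists were planned.

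Beyond the genes named by the rule, the transcription factor Nkx6-1 rose by 0.74 and the retinaldehyde dehydrogenase Aldh1a1 by 0.88 at day 4, and the semaphorin Sema4d at -1.90 and its receptor family member Plxnb3 at -1.87 fell. At day 15 the neuropeptide gene Npy rose by 0.91 and the splicing factor Rbfox2 by 1.09.

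Lists not described so far were called for day in wild type. Myelin glycolipid synthesis had 14 of 16 genes higher (median 0.85, adjusted p = 2.72e-08, adjusted p = 0.223 with an estimated correlation), cholesterol synthesis 14 higher and 1 lower of 19 (median 0.40, adjusted p = 0.000157, adjusted p = 0.584 with an estimated correlation), newly formed oligodendrocytes 7 of 18 higher (median 0.31, adjusted p = 0.0176, adjusted p = 0.673 with an estimated correlation) and astrocytes 10 higher and 4 lower of 18 (median 0.26, adjusted p = 0.0271, adjusted p = 0.509 with an estimated correlation). Wnt ligands, receptors and transducers had 7 higher and 24 lower of 48 (median -0.20, adjusted p = 0.0233, adjusted p = 0.379 with an estimated correlation), motor neuron genes 6 of 14 lower (median -0.18, adjusted p = 0.0176, adjusted p = 0.53 with an estimated correlation), meninges and fibroblast genes 1 higher and 8 lower of 14 (median -0.81, adjusted p = 0.0271, adjusted p = 0.775 with an estimated correlation), and the amino acid and endoplasmic reticulum stress list 6 higher and 1 lower of 16 (median 0.22, adjusted p = 0.0412, adjusted p = 0.581 with an estimated correlation). At day 4, ependyma genes had a median genotype difference of 0.28 with Enkur alone called of 11 (2 higher and 0 lower adjusted over the list alone; adjusted p = 0.00106, adjusted p = 0.53 with an estimated correlation).

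For the difference between days, medians were 0.059 for glycolipid synthesis (2 of 16 genes called higher and 0 lower; adjusted p = 8.06e-05, adjusted p = 0.391 with an estimated correlation), -0.19 for microglia and macrophage genes (0 of 18 called; adjusted p = 0.000288, adjusted p = 0.47 with an estimated correlation) and 0.087 for pericyte and smooth muscle genes (0 of 11; adjusted p = 0.0392, adjusted p = 0.615 with an estimated correlation). They were 0.13 for astrocytes (0 of 18; adjusted p = 0.0113, adjusted p = 0.453 with an estimated correlation), 0.082 for neurons (0 of 19; adjusted p = 0.0173, adjusted p = 0.615 with an estimated correlation), 0.064 for endothelium (0 of 13; adjusted p = 0.0156, adjusted p = 0.393 with an estimated correlation) and 0.24 for meninges and fibroblasts (0 of 14; adjusted p = 0.0397, adjusted p = 0.622 with an estimated correlation). Schwann cell genes had a median of 0.29 (0 of 9; adjusted p = 0.00539, adjusted p = 0.241 with an estimated correlation), ependyma genes of -0.25 (0 of 11; adjusted p = 0.00957, adjusted p = 0.492 with an estimated correlation) and cartilage and bone genes of 0.31 (0 of 12; adjusted p = 0.00599, adjusted p = 0.492 with an estimated correlation). With the Eif2s3y covariate the medians of glycolipid synthesis and of pericyte and smooth muscle genes turned to -0.042 and -0.053. Without the 3 arrays with RNA of 1 sex the median of pericyte and smooth muscle genes was -0.020.

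At the genotype contrast of day 4 the other lists were not called. Meninges and fibroblast genes had a median of 0.29 with 13 of 14 of positive sign (adjusted p = 0.215). Adjusted p was 0.206 for motor neuron, 0.16 for microglia and macrophage, 0.94 for pericyte and smooth muscle, 0.673 for Schwann cell, 0.373 for the amino acid and endoplasmic reticulum stress response, 0.342 for cell cycle, 0.588 for reactive astrocyte, 0.673 for neuron, 0.21 for immature nervous system, 0.467 for lipid-laden phagocyte, 0.342 for endothelium, 0.215 for red blood cell, 0.125 for cartilage and bone, 0.227 for interferon response, 0.893 for immediate early genes, 0.76 for brachial and thoracic Hox, 0.212 for lumbosacral Hox and 0.972 for sex-linked genes.

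Single arrays stood apart by other tissues and by sex. Acta1, the actin of skeletal muscle, was at 13.17, 6.42 and 10.64 on the Olig2cre/DA-Cat day 15 arrays and at 8.00, 6.43 and 9.08 on those of wild type. Without Olig2cre/DA-Cat day 15 replicate 1, the array highest in Acta1, 375 genes differed at day 15, 76 higher and 299 lower. Xist was at 5.49 on Olig2cre/DA-Cat day 4 replicate 2 and 5.64 on wild type day 15 replicate 2, and Eif2s3y at 3.29 on Olig2cre/DA-Cat day 15 replicate 2.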
